A study of Mus musculus with 82 samples.

How the data were processed

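The series followed mouse embryonic fibroblasts (OG2-MEFs in the labels) during reprogramming toward pluripotency with retroviral OSKM, the transcription factors Oct4, Sox2, Klf4 and c-Myc. It holds 82 samples, of which 8 are ATAC-seq libraries, and only the peak lists of those 8 were analysed here. ATAC-seq marks accessible chromatin by the insertion of sequencing adapters with a transposase. The RNA-seq, R-loop mapping and CLIP-seq samples of the series were not used here. The ATAC-seq samples fall into 4 groups of 2 replicates: OSKM with Flag or with RNase H1(D209N), each at day 3 and at day 7. RNase H1 cuts the RNA of RNA:DNA hybrids, and the D209N form carries a substitution in its catalytic site. The series design text names a control beside the RNase H1 forms, and the groups labelled Flag are read here as that control.

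The authors deposited 1 peak list per group, with the chromosome, start, end and name of each interval and no score, signal or read count. The submitters' processing notes name CASAVA, Bowtie2 2.3.2 and the mm10 and GRCm38.p5 builds. The peak caller, its threshold, the handling of insertion offsets and the way the 2 replicates were combined are not given in the sources used here. Each list was matched to its group by the arm and day inside the peak names. Every name carries rep1 and a serial number that ascends along the file with gaps, and between 146 and 180 names per list stand on separate intervals. Such gaps are what removal of replicate 1 peaks after calling would leave, but no label or header records that step. The span of serial numbers on each chromosome was summed to count the peaks numbered, and the share of numbers still present was called the kept share. Intervals on the mitochondrial genome (3 per list) were left out, and chromosomes 1 to 19, X and Y were used. Read depth is unknown, so no value could be set against it.

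With 1 list per group there was no replicate spread, so no test between conditions was made and no p-value is given. Shares carry Wilson 95% intervals from scipy, which cover counting error only. Overlap meant at least 1 bp in common and was computed in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, in place of the bedtools step written in the plan. It was set beside 100 copies of the other list shifted around each chromosome at random. The 4 lists were merged into 1 set of union regions, each present in or absent from each list. A region was called gained in an arm when present at day 7 and absent at day 3, lost in the opposite case, and kept when present on both days.

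Genes came from the RefSeq gene table of GRCm38.p6, which shares the main chromosomes of the files' build and gives the outer ends of each gene without strand or exons. The plan, written before the data were examined, had named transcription start sites, exons and sequence motifs. Start sites were replaced by both annotated gene ends, the exon check of the vector genes by peaks touching the gene, and the motif shares were not run, because the genome sequence was not used here. A peak within 1 kb of an end overlapped 55.9% of protein-coding genes in the Flag day 3 list, against 11.9% when gene coordinates were moved by 20 kb, so the coordinates fit the build. Each peak was assigned to the protein-coding gene with the nearest end within 100 kb of its centre. A gene-end peak overlaps the 1 kb around either end, and may be assigned to a neighbouring gene.

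For 17 gene groups fixed beforehand, the mean difference in assigned peaks was placed among 10000 random groups of the same size, matched on deciles of total peaks. This percentile describes these 4 lists and is not a test between conditions. Groups were not matched on gene-end peaks at day 3, so a group with few of them had more room to gain. Percentiles below 2.5 or above 97.5 are called outside the central 95%. Over the 34 arm comparisons of groups, 1.7 would lie outside by chance, and over all 68 comparisons 3.4 would. The groups were pluripotency, epithelial, mesenchymal, fibroblast extracellular matrix, AP-1 factors, R-loop processing, p53 and DNA damage response, interferon response, cell cycle, housekeeping, neural, endoderm, trophoblast, muscle, macrophage and blood, endothelial, and keratinocyte. In the interferon response group, 18 of 20 symbols were found as protein-coding genes. Tested on simulated data for the day 3 arm comparison over 21887 genes, with 20 runs for each group, the step placed 94.1% of groups with halved peaks below the central 95% and 5.0% of unchanged groups outside. The halved groups were placed below in 10 of 20 runs for macrophage and blood, 15 for keratinocyte and 19 or 20 for the others. The simulated D209N counts were thinned Flag day 3 counts with no peaks of their own. Real lists can vary more, so the share found may be lower in them. Gene-end peaks and changes between days were not simulated.

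Named genes followed a fixed rule. For each arm comparison and each day comparison they are members of the pluripotency, epithelial, mesenchymal, fibroblast extracellular matrix and R-loop processing groups whose gene-end peak differed, with the 5 genes of largest positive and the 5 of largest negative difference in assigned peaks. Pou5f1, Sox2, Klf4, Myc, Rnaseh1, Nanog, Cdh1 and Thy1 are reported throughout. For each arm comparison the 5 regions present in 1 arm only with the most base pairs under peaks of that list were listed as well. A gene-end difference is said to rest on the edge of a peak where the other list has a peak overlapping it outside the window. Alternatives changed the overlap rule, the width asked of a peak, the joining distance, the gene-end window, the assignment limit and the measure per gene. Figures were drawn with matplotlib 3.10.9.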

Results

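Accessible chromatin was mapped in fibroblasts given OSKM with Flag or with RNase H1(D209N), called D209N below, at days 3 and 7. The Flag list held 36375 peaks at day 3 and 42439 at day 7, and the D209N list held 29189 and 40452. Median peak width lay between 464 and 489 bp. The 4 lists merged into 55272 regions, of which 21785 were present in all 4, and 50.0% of those lay within 1 kb of an annotated gene end. Each condition has 1 list, so no value below has a replicate error, and intervals cover counting error only. A gene without a listed peak may still be accessible below the calling threshold.

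The loci of the delivered factors had peaks in every list. Pou5f1, which encodes Oct4, had 3 assigned peaks in each list and Klf4 had 4 in each. Myc had 7 peaks in 3 of the lists and 6 in D209N day 7. Sox2 had 4 peaks in Flag day 3, 2 in D209N day 3, 6 in Flag day 7 and 5 in D209N day 7. Rnaseh1, at chromosome 12 from 28649601 to 28659592, had 1 peak in every list, also in the lists of cells given its mutant form. Peaks touching the gene itself numbered 1 in each list for Pou5f1 and Rnaseh1, 2 for Klf4, 1 or 2 for Sox2 and 2 or 3 for Myc. Reads of the delivered cDNA could map to exons of these genes, so such peaks may come from the vector. Without exons in the gene table, vector and endogenous peaks could not be told apart. Nanog, a pluripotency factor, had 2, 1, 2 and 3 peaks in the same order, and none of these lay at a gene end. Thy1, a fibroblast surface marker, had 1, 2, 4 and 4.

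The day 3 comparison asks how the chromatin of D209N cells differed from that of Flag cells early in reprogramming. Sall4, a transcription factor of pluripotent cells at chromosome 2 from 168748332 to 168767201, had 3 peaks in the Flag list and 0 in the D209N list. Cdh1, which encodes the epithelial adhesion protein E-cadherin (chromosome 8, 106603350 to 106670247), had 4 peaks in Flag and 1 in D209N, and its gene-end peak was absent from the D209N list. Utf1, Nr0b1 and Grhl2 also had a gene-end peak in Flag only, as did the mesenchymal genes Runx2, Tagln, Tgfb1 and Twist2 and the collagen gene Col5a1. Col3a1, Col6a1 and Loxl1, genes of fibroblast matrix, had a gene-end peak in D209N only. Ap1m2 counted as Flag only by the edge of its peak, since a D209N peak overlapped it outside the 1 kb window.

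Of 35 pluripotency genes, 0 had more assigned peaks in D209N at day 3, 14 had fewer and 21 had the same number. Their mean difference was -0.686 peaks per gene, against -0.385 in matched random groups, at percentile 2.5, which is on the limit and was not counted as outside. In 100 thinnings of the Flag list the median percentile was 3.22, and 38 of them placed the group outside. Gene-end peaks were present at 16 of these genes in Flag and 13 in D209N, at percentile 24.0, and over all coding genes at 12243 and 11319. Among 26 epithelial genes 4 had more and 7 fewer, at percentile 87.8, and among 24 mesenchymal genes 3 had more and 11 fewer, at percentile 43.3. AP-1 factors, which include Fos and Jun and are active in fibroblasts, had a mean difference of 0 where matched groups had -0.712, at percentile 97.8. It lay inside when peaks were assigned within 20 kb (96.1), when gene-end peaks were counted (71.5) and in the median of 100 thinnings of the Flag list (94.1), which left an excess of 0.646 peaks against 0.712. With peaks assigned to the nearest gene body it stayed outside, at 98.2. Fibroblast extracellular matrix genes lay at percentile 56.0 by assigned peaks and at 99.7 by gene-end peaks, with 16 of 22 in D209N and 14 in Flag. R-loop processing genes had a gene-end peak at 21 of 22 genes in both lists and lay at percentile 29.6.

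The genes with the largest deficit in D209N at day 3 were Bcor, a subunit of a Polycomb complex, with 5 peaks against 13 in Flag, and Creb3l2, also 5 against 13. Zbtb7c had 11 against 18, Zswim6 9 against 16 and Arntl, a circadian clock factor, 8 against 15. The largest excesses were smaller: Cdk19, Mrtfb, Col16a1 and Runx1t1 each had 6 peaks in D209N against 3 in Flag, and Epdr1 had 8 against 5. Within 20 kb the deficits of Bcor, Zbtb7c and Zswim6 were 2 peaks, that of Creb3l2 was 3 and that of Arntl 4. In 100 thinnings of the Flag list to the D209N length the mean differences were -5.45 for Bcor, -5.33 for Creb3l2, -3.43 for Zbtb7c, -3.66 for Zswim6 and -3.91 for Arntl. Net differences of at least 4 regions occurred at 154 genes. This lay within the 123 to 178 found when arm labels were reassigned at random, with each arm-only region kept at its gene.

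The D209N day 3 list had 0.802 times the peaks of the Flag list, with autosomes between 0.766 and 0.873 and chromosome X at 0.741. Of the Flag peaks 71.6% (71.1 to 72.1) overlapped a D209N peak, and of the D209N peaks 89.7% (89.4 to 90.1) overlapped a Flag peak, against 1.201% and 1.505% for shifted copies. Regions in Flag only numbered 10001 and regions in D209N only 2823. Among Flag-only regions the most base pairs under peaks lay on chromosome 7 from 123083440 to 123084909, inside a gene, with Tnrc6a the nearest coding gene end. A Flag-only region on chromosome 13 from 71962882 to 71964078 lay at a gene end, 0.2 kb from Irx1. Among D209N-only regions the most lay on chromosome 19 from 37959306 to 37960285, inside a gene, 60.8 kb from the end of Myof, in a region present in both day 7 lists. The names of the D209N list keep 79.5% of their serial numbers and those of the Flag list 90.0%, and by numbered peaks the ratio was 0.907.

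**Figure D1:**
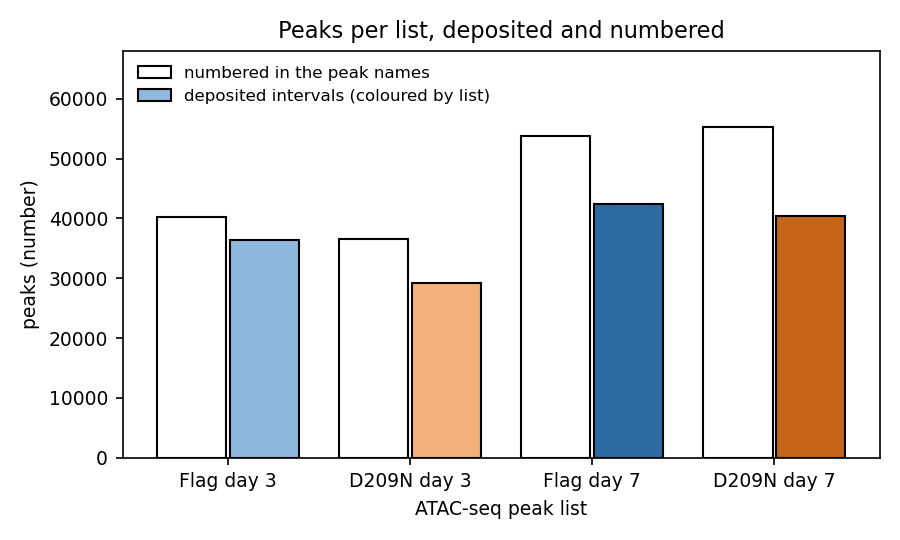
Number of peaks in each of the 4 ATAC-seq peak lists, with open bars for peaks numbered in the names and filled bars for deposited intervals. At day 3 D209N is below Flag by both counts, and at day 7 it is below by deposited intervals (40452 against 42439) and above by numbered peaks (55198 against 53838).

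The day 7 comparison puts the same question later in reprogramming. The Sall4, Utf1, Cdh1 and Grhl2 gene-end peaks that D209N lacked at day 3 were present in both day 7 lists, and that of Nr0b1 was in neither. Cdh1 had 6 peaks in D209N and 2 in Flag. Zfp42, a marker of pluripotent cells, and Eras had a gene-end peak in D209N only, while Prdm14, a germline and pluripotency regulator, had it in Flag only. Runx2, the osteoblast regulator, and Postn, a matrix protein, had a gene-end peak in Flag only, and Col3a1 and Col6a1 in D209N only. Among epithelial genes Krt19, a keratin, had it in D209N only. Dnmt3l counted as D209N only and Tjp3, a tight junction protein, as Flag only by the edge of a peak alone.

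Pluripotency genes with more assigned peaks in D209N at day 7 numbered 5, with fewer 8 and equal 22, at percentile 51.7. By gene-end peaks, 18 of 35 in D209N against 16 in Flag placed the group at percentile 98.1, and without the edge-only difference of Dnmt3l it lay inside, at 90.7. Epithelial genes divided into 6 with more and 7 with fewer, at percentile 69.9, and 19 of 26 had a gene-end peak in each list. Mesenchymal genes divided into 5 and 11, at percentile 7.25, and fibroblast extracellular matrix genes into 4 and 6, at percentile 41.8. R-loop processing genes lay at percentile 41.0 and AP-1 factors at 38.9. No group of the 17 lay outside the central 95% by assigned peaks at day 7. Over the 34 arm comparisons of both days, 1 lay outside by assigned peaks and 2 by gene-end peaks, where 1.7 would by chance.

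Spink13 had 10 peaks in D209N against 3 in Flag, Tgfbr3, a TGF-beta co-receptor, 11 against 6, Tead1, a Hippo pathway transcription factor, 19 against 15, Irf2bp2 16 against 12 and Trio 12 against 8. In the other direction Rap1gap2 had 8 against 14, Casz1 9 against 15, Slc23a2, a vitamin C transporter, 2 against 8, Med13l 13 against 18 and Sh3pxd2a 13 against 18. Within 20 kb the differences of Trio and Sh3pxd2a were 0, that of Irf2bp2 was 1 and the others were 2 or 3 peaks in size. Net differences of at least 4 regions occurred at 69 genes, within the 44 to 87 of random reassignments of the arm labels. There were thus no more such genes than random labels gave.

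By number the day 7 lists lay closer, with 0.953 times as many peaks in D209N as in Flag. Of Flag peaks 82.3% (81.9 to 82.6) overlapped D209N and of D209N peaks 86.1% (85.7 to 86.4) overlapped Flag. Flag-only regions numbered 7437 and D209N-only regions 5557. The most base pairs under peaks in Flag only lay at a gene end 0.4 kb from the collagen gene Col24a1 (chromosome 3, 145292421 to 145293308), and the most in D209N only lay between genes 25.9 kb from Rcl1 (chromosome 19, 29074857 to 29076100). The order of the arms turned when only peaks above the median width were counted, to 1.017, and by numbered peaks, to 1.03. Regions in 1 arm only turned as well, to 276 in Flag and 317 in D209N, with that width asked only of the arm that held them.

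Between day 3 and day 7 Flag cells acquired gene-end peaks at epithelial genes. Esrp1 and Esrp2, splicing regulators of epithelial cells, Ocln, a tight junction protein, and Spint1, Marveld3 and Ovol1 had a gene-end peak at day 7 and not at day 3, and Tjp3 by the edge of a peak. Of 26 epithelial genes 17 had more assigned peaks at day 7 and 1 had fewer, and gene-end peaks went from 12 to 19 genes. Over all coding genes gene-end peaks went from 12243 to 13452. The group lay at percentile 95.7 by assigned peaks, inside the central 95%, and at 99.9 by gene-end peaks and 98.6 within 20 kb, both outside. The gene-end percentile is limited because random groups were not matched on gene-end peaks at day 3. By nearest gene body it lay at 94.97, and at a median of 95.3 with the day 7 list thinned to the day 3 length. Among pluripotency genes Fgf4 and Prdm14 gained and Nr0b1 and Zfp42 lost a gene-end peak, with the group at percentile 6.43. Sparc and Postn, matrix genes, gained a gene-end peak, and Loxl1 by the edge of a peak, while 18 of 24 mesenchymal genes had one on both days.

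The genes with the largest increase in the Flag lists were Septin9, from 8 to 22 peaks, Arhgef10l, from 5 to 16, Rhou, from 10 to 20, Sipa1l2, from 9 to 18, and Sh3pxd2a, from 9 to 18. Atp10a went from 20 to 12, Ndst3 from 8 to 2, Mllt3 from 13 to 8, and Sptssb and Socs6 each from 10 to 5. Within 20 kb the increases were between 1 (Sh3pxd2a) and 4 (Arhgef10l), and the falls were 1 for Ndst3 and Mllt3, 2 for Atp10a and 3 for the others. Net differences of at least 4 regions occurred at 445 genes, above the 342 that was the highest of random reassignments of the day labels. Gained regions numbered 14337, lost regions 8168 and kept regions 27711. Lost regions lay at gene ends in 7.30% (6.75 to 7.88), gained regions in 17.9% (17.3 to 18.6) and kept regions in 44.4% (43.9 to 45.0).

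In D209N cells the same epithelial genes Esrp1, Esrp2, Ocln, Spint1, Marveld3 and Ovol1 had a gene-end peak at day 7 and not at day 3, together with Cdh1, Grhl2 and Krt19, and Ap1m2 by the edge of a peak. Epithelial gene-end peaks went from 9 to 19 of 26 genes, at percentile 99.98, while by assigned peaks 13 genes had more and 2 fewer, at percentile 90.9. Over all coding genes gene-end peaks went from 11319 to 13223. Random groups were again not matched on gene-end peaks at day 3. Sall4, Utf1, Eras, Fgf4 and Dnmt3l gained a gene-end peak, and of 35 pluripotency genes 16 had more assigned peaks and 3 fewer, at percentile 46.1. Twist2, Tgfb1, Tagln, Col5a1 and Sparc gained a gene-end peak as well. Neural genes had 13 of 15 members with more peaks, at percentile 98.3 and with an excess of 0.790 peaks over matched groups. With the day 7 list thinned the median percentile was 97.0, inside. The mean excess was then 0.678, and 41 of 100 thinnings placed the group outside. The Flag lists placed neural genes at 91.9. By gene-end peaks 4 of the 15 genes gained one in each arm, at percentile 99.0 in Flag and 95.1 in D209N. The percentiles differ because matched groups gained 0.0654 per gene in Flag and 0.109 in D209N.

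**Figure D2:**
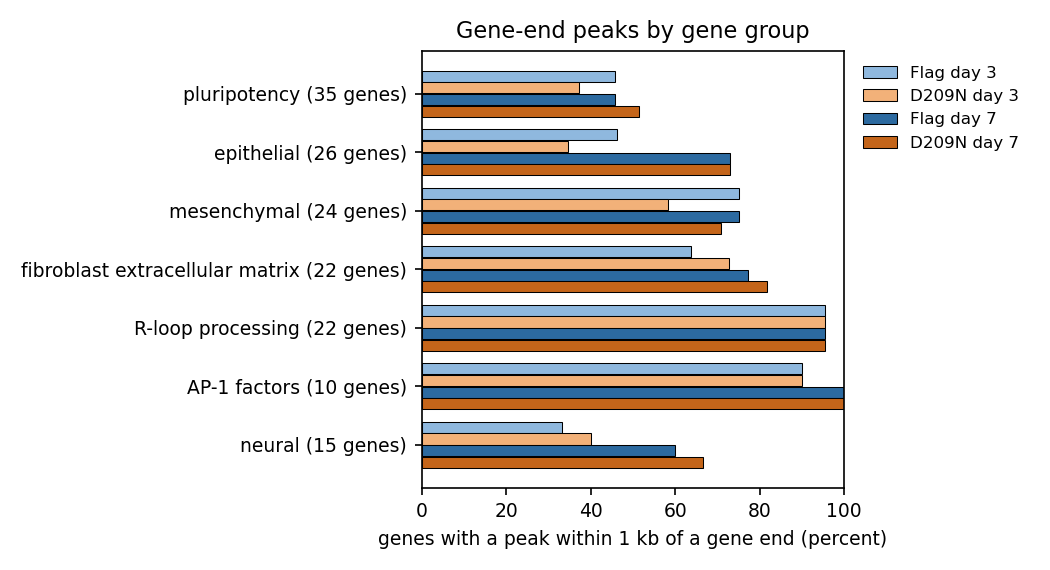
Percent of genes in 7 of the gene groups with a peak within 1 kb of an annotated gene end, by list, with the number of genes in brackets. Epithelial genes had such a peak at 12 (Flag) and 9 (D209N) of 26 genes at day 3 and at 19 in both arms at day 7, and R-loop processing genes at 21 of 22 in every list.

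Rybp, a Polycomb subunit, went from 2 to 15 peaks in D209N, Rbm20 from 2 to 14, Mvb12b from 1 to 13, Tns3 from 10 to 21 and Septin9 from 7 to 18. Sptssb went from 11 to 4, Hpgd from 9 to 4, Slit2, an axon guidance ligand, from 8 to 3, Syne1 from 8 to 3 and Epdr1 from 8 to 3. Within 20 kb the increases were between 2 (Rybp) and 6 (Rbm20 and Tns3), and the falls between 1 (Slit2) and 5 (Sptssb). In 100 thinnings to the day 3 length the increase of Tns3 had a mean of 5.26, between -2 and 11. Net differences of at least 4 regions occurred at 596 genes, above the 553 that was the highest of random reassignments of the day labels. The D209N lists gained 16091 regions, lost 4624 and kept 24077, and gene ends held 20.5% (19.9 to 21.1), 6.73% (6.04 to 7.48) and 46.6% (46.0 to 47.2) of them. Gained regions outnumber those of Flag only when each arm is set against its own day 3 list. Set against the day 3 lists of both arms together, they numbered 10893 in D209N and 12787 in Flag, and regions listed in both arms at day 3 and lost numbered 3267 in D209N and 3422 in Flag.

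**Figure D3:**
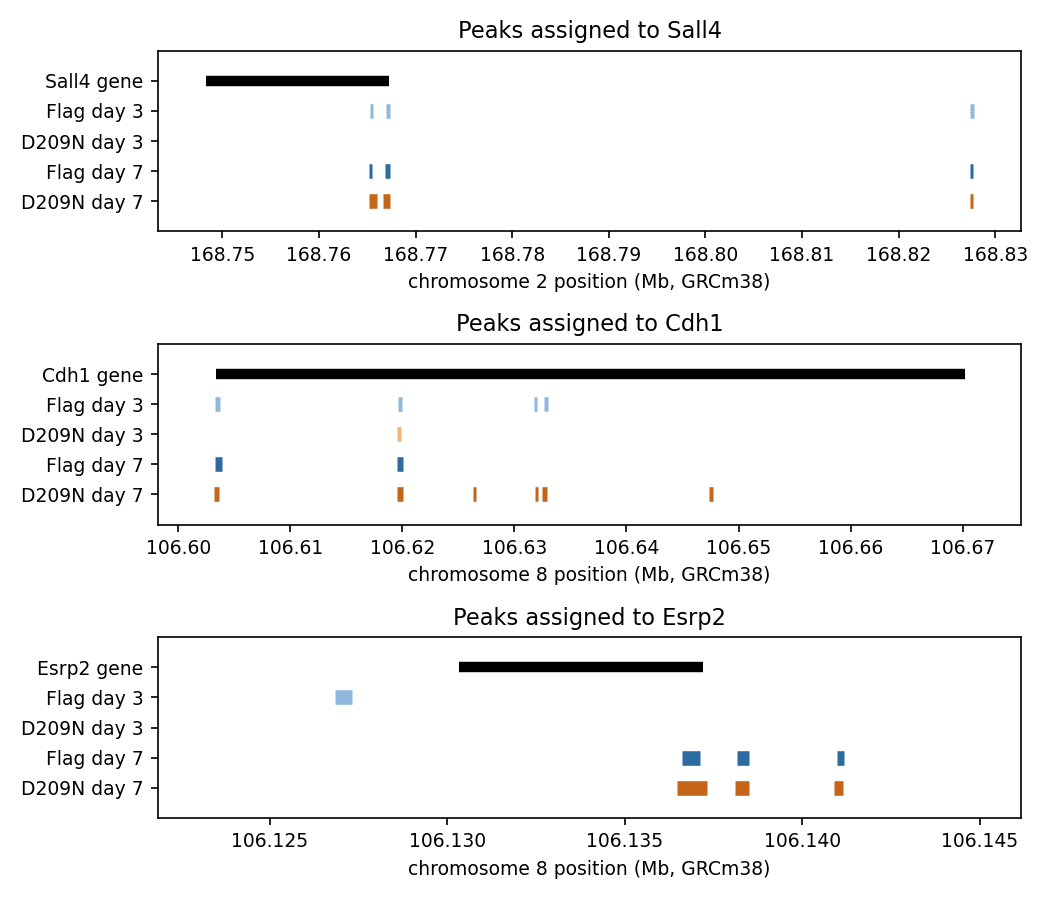
Peaks assigned to Sall4, Cdh1 and Esrp2 in the 4 lists along the chromosome (Mb, GRCm38), with the annotated gene in black; the narrowest intervals are drawn wider than scale so that they can be seen. Sall4 has 0 peaks in D209N day 3 and 3 in each other list, Cdh1 has 4, 1, 2 and 6 from top to bottom, and Esrp2 has a gene-end peak in both day 7 lists.

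The last comparison asks how far D209N cells held the openings and closings of Flag cells. Of 14337 regions gained in Flag, 58.3% (57.5 to 59.1) were present in D209N at day 7, and of 16091 gained in D209N, 71.9% (71.2 to 72.6) were present in Flag. Among the Flag-gained regions the share was 80.9% where D209N had listed the region at day 3 and 55.6% where it had not. Among D209N-gained regions that Flag had not listed at day 3, 65.3% (64.4 to 66.2) were present in Flag at day 7. Esrp2, Ocln and Fgf4 are genes whose gene-end peak was gained in both arms, and Postn and Prdm14 are genes where it was gained in Flag only. Of 8168 regions lost in Flag, 19.1% (18.3 to 19.99) were present in D209N at day 7, and of 4624 lost in D209N, 20.9% (19.8 to 22.1) were present in Flag. Where the other arm had listed the lost region at day 3, the shares were 24.1% (22.7 to 25.6) in D209N and 20.5% (19.2 to 22.0) in Flag. The 2596 regions lost in both arms lay at gene ends in 4.93%, a median of 47.4 kb from the nearest coding gene end, and the 7110 gained in both lay there in 19.8%, at a median of 13.7 kb.

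The day 7 balance of the arms differed with the day 3 state. Among regions listed in neither arm at day 3, 5677 were in Flag only and 3783 in D209N only, a ratio of 1.501 (1.44 to 1.56). Among regions listed in both arms at day 3, 671 were in Flag only and 826 in D209N only, a ratio of 0.812 (0.734 to 0.899). The ratio was 1.08 (0.975 to 1.19) among regions listed in Flag only at day 3 and 1.40 (1.17 to 1.67) among those listed in D209N only. Over all regions listed in any arm at day 3, 1760 were in Flag only and 1774 in D209N only. Of the Flag-gained regions with a Flag day 7 peak above the median width, 89.6% were present in D209N by a peak of any width. The width was not asked of the D209N list, so this share does not compare like with like.

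**Figure D4:**
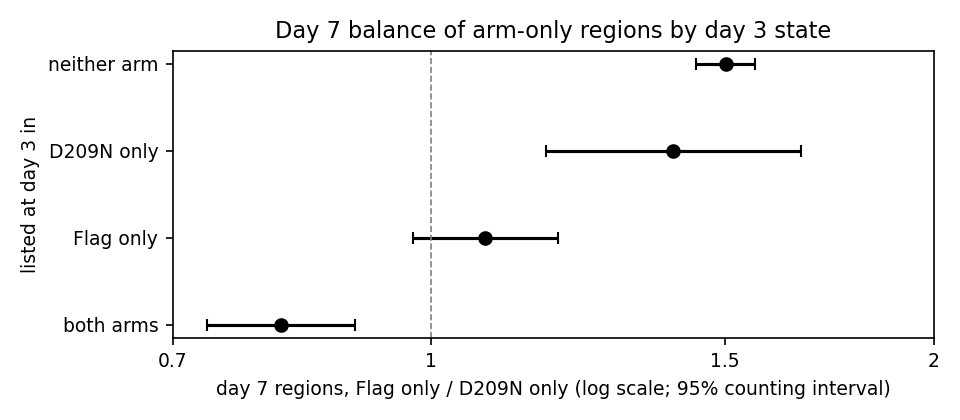
Ratio of day 7 regions in Flag only to those in D209N only (log axis), by the arms in which the region was listed at day 3, with 95% counting intervals as bars. The ratio is 1.501 for regions listed in neither arm, 1.40 for D209N only, 1.08 for Flag only and 0.812 for both.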

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

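The rule that picked these genes was set after the lists had been seen. The tests of random arm labels and of wider chromosome stretches were set before their results were seen. For 10 of the 72 named genes the number of assigned peaks went one way from day 3 to day 7 in Flag and the other way in D209N. With 1 list per group the difference was not tested. The change in D209N minus the change in Flag was 7 for Cdh1, 9 for Creb3l2, 8 for Spink13, 7 for Zswim6, 6 for Tgfbr3, 6 for Trio and 3 for Zfp42. It was -7 for Slc23a2, -3 for Rap1gap2 and -2 for Postn. Creb3l2, Zswim6, Spink13, Tgfbr3, Trio, Slc23a2 and Rap1gap2 were named for a large arm difference at day 3 or day 7. That difference is a part of this value, so its size follows in part from how the genes were chosen. Over all 16336 genes with a peak, 970 went opposite ways and 5322 the same way.

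Several of these genes are those with a net difference of at least 4 arm-only regions at day 7. Random arm labels could account for the number of such genes. With each arm-only region kept at its gene, random reassignment of the labels gave between 44 and 87 genes, and 69 were observed. Whether arm-only regions gather at genes whatever their arm was not tested. Pooled over these 69 genes, arm-only regions 1 to 5 Mb away exceeded the genome-wide share of the gene's own arm by only 0.764 percentage points (-0.854 to 2.37). No wider change of chromosome, such as a copy number change, common to these genes was thus seen. Genes picked by chance would give the same result, and their number was no higher than random labels gave, so no cause is excluded. A region near several genes was counted for each, so the interval may be too narrow. Pooling cannot exclude a wider change at a few of these genes, nor one that stays within 1 Mb. A biological difference at any of these genes stays open and untested, and the count gives no ground for it.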

How the results depend on the processing

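Alternatives planned before the data were examined were joined by numbered peaks, a day 3 state from both arms, assignment to gene bodies, repeated thinning and gene-end differences without those due to the edge of a peak, which were chosen after seeing the data. No paired analysis was possible because each group has 1 list, and leaving out replicates could not be run for the same reason; motif shares were not run. The cause of the changes below was not tested. Read depth, which is unknown, limits every absence.

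The D209N to Flag peak ratio moved from 0.802 to 0.780 (peaks above the median width) and 0.907 (numbered peaks) at day 3, and reversed from 0.953 to 1.017 and 1.03 at day 7. Overlap of Flag and of D209N peaks moved to 65.9% and 87.0% at day 3 and 78.6% and 81.7% at day 7 with 50% of the peak covered, to 64.0%, 79.7%, 74.6% and 78.3% with reciprocal overlap, and to 94.3%, 99.0%, 98.5% and 98.6% in the widest part of each list. With a peak above the median width required, Flag-only and D209N-only regions numbered 987 and 126 at day 3 (ratio 0.128 in place of 0.282) and 276 and 317 at day 7 (ratio 1.15, reversed from 0.747). The width was asked only of the list that held the region, and absence meant no peak of any width. The day 7 ratio was 0.805 with 50% of the region covered. By the same width rule gained regions numbered 1839 in Flag and 3165 in D209N, and lost regions 1486 and 646. Of such Flag-gained and Flag-lost regions, 89.6% and 26.4% were present in D209N at day 7 by a peak of any width. The Flag-gained share was 59.2% in the union merged at 200 bp, and lost Flag regions numbered 3422 with the day 3 state from both arms. Gene-end shares of lost and gained Flag regions moved to 15.5% and 29.8% within 2.5 kb of an end. With ends of protein-coding genes only they were 3.71% and 11.9%. The matching D209N shares were 14.6% and 32.3%, then 3.20% and 14.3%, and lost stayed below gained throughout. Regions in all 4 lists moved to 57.9% and 44.2%.

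Of the 34 arm comparisons of groups, 1 lay outside the central 95%, with 0 within 20 kb, 0 after 1 thinning and 2 by gene-end peaks, also without edge-only differences, where macrophage and blood (day 3) took the place of pluripotency (day 7). Over 100 thinnings at day 3, pluripotency lay outside in 38, AP-1 factors in 25 and housekeeping in 24, each with its median inside. Of the day comparisons 1 lay outside, with 4 within 20 kb and 5 by gene-end peaks, again with or without edge-only differences. Within 20 kb, 27 of the 40 named gene differences shrank below 50% of their size, with Trio and Sh3pxd2a (day 7 arms) at 0 and Septin9 in Flag and Rybp in D209N at 2, and none changed sign; in the mean of 100 thinnings 2 of 40 shrank as far.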

Other observations

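The tests below that concern removed peaks, weak sites and detection were chosen after the result was seen, and those on region width, gene-end distance and list length before. Detection was first judged on the 0.812 for regions listed in both arms, which is part of the pattern itself, and that test was replaced. Whether the day 3 loss gathered at the fixed gene groups was also tried and dropped as undecidable. The counts were 0 groups below the central 95% and 1.80% of the net deficit at genes holding 1.92% of the assigned Flag day 3 peaks, too few to make up the deficit.

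By assigned peaks, the remaining gene groups lay inside the range of matched groups between arms. At day 3 the p53 and DNA damage response group lay at percentile 85.1, interferon response at 66.8, cell cycle at 10.5 and housekeeping at 92.7. Neural genes lay at 33.4, endoderm at 7.70, trophoblast at 87.1, muscle at 54.3, macrophage and blood at 93.7, endothelial at 95.1 and keratinocyte at 36.9, all inside the central 95%. At day 7 these groups lay between 11.6 (macrophage and blood) and 88.2 (cell cycle).

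Sox1, a transcription factor of neural progenitors, was chosen after its values were seen, and had 0 peaks in Flag and 1 in D209N at day 3 and 4 and 5 at day 7. Between the days 4 genes of the neural group gained a gene-end peak in each arm, at percentile 99.0 in Flag and 95.1 in D209N. Within 20 kb the group lay at 99.4 and 98.6. In D209N the housekeeping group, with 15 of 16 genes at day 3 and 14 at day 7, lay at 0.555, and the macrophage and blood group, with 4 and 3 of 12, at 0.730. Each of these values rests on 1 gene that lost its gene-end peak, Actb and Tal1. Actb lost it between the days in Flag as well, while Tal1 gained one in Flag. Groups were not matched on gene-end peaks at day 3, and the housekeeping group had little room to gain. The neural group had more room, with such a peak at 5 (Flag) and 6 (D209N) of 15 genes at day 3. Shared day 3 regions were narrower in D209N, with a median width ratio of 0.902, and wider in Flag for 68.5% of 25878 regions, while at day 7 the ratio was 1.00.

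The shorter D209N day 3 list has 2 candidate explanations that were tested. Removal of peaks after calling is not the whole cause, since numbered peaks already stood at 0.907 (0.853 to 0.949 over autosomes), although the kept share adds a ratio of 0.883. Weak sites under the calling threshold may contribute: among regions of Flag day 3 and both day 7 lists, those missing from D209N day 3 were 41.2% in the narrowest of 5 width classes and 3.18% in the widest, 13.0 times as many. For regions of D209N day 3 and both day 7 lists, those missing from Flag day 3 were 16.8% in the narrowest class and 0.391% in the widest. The missing shares were thus higher for D209N in both classes. The converse ratio for the Flag list was 42.9, so a rise toward narrow regions occurs in both lists. The ratio therefore cannot tell weak sites in D209N from a trait of any list. A biological difference between the arms stays open and was not tested.

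At day 7 regions listed in neither arm at day 3 leaned to Flag and regions listed in both leaned to D209N, with an odds ratio of 1.85 (1.66 to 2.06), while those listed in 1 arm at day 3 did not lean to D209N. Lower detection throughout the D209N day 7 list stays open, since the ratio of Flag-only to D209N-only over all regions listed in any arm at day 3 was 0.992 (0.929 to 1.06). Peaks numbered at day 7 were not fewer in D209N, at 55198 against 53838 in Flag. The kept share was lower, at 73.0% against 78.5%, and its part in the lean to Flag was not tested. With the Flag day 3 list cut to the D209N length, the ratio for regions listed in both was 0.764 (0.683 to 0.855). These 23820 regions are a subset of those that gave 0.812, and regions listed in neither arm were not counted again. The test therefore cannot decide whether a stricter D209N day 3 list plays a part. Pooled within deciles of region width the odds ratio was 1.41 (1.21 to 1.63), and within deciles of distance to gene ends it was 1.77 (1.59 to 1.98). Width therefore does not account for all of the pattern. How much it accounts for cannot be told, because merging peaks of more lists itself widens a region. Median widths were 243 and 246 bp for regions listed in neither arm at day 3 and 480 and 514 bp for those listed in both. A difference between the arms themselves stays open and was not tested.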
